A study of Mus musculus with 30 samples.

How the data were processed

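Total RNA (60 to 80 ng) of mouse lumbar dorsal root ganglia, collected after perfusion with RNAlater, was depleted of ribosomal RNA with Ribo-Zero Plus and sequenced as stranded libraries, per the labels. The submitters' processing notes name FastQC 0.12.1, STAR 2.7.10b and StringTie 2.2.1, and the builds mm10 and GRCm39 without their roles. The deposited table gives TPM per gene, a unit that scales each library to 1e+06, and its columns summed to 999910 to 999941. Coordinates are printed as the table gives them, and the start of Gnai3 matched GRCm39. The number of reads per library is not stated, so the depth is unknown and counting error was not computed.

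Samples were grouped by drug and day from the labels, giving 10 groups of 3. All 30 columns were used. Of 56686 genes, 19144 were at 0 in every library. For 882 repeated gene symbols the most abundant entry was kept for the lists. Genes with a TPM of at least 1 in at least 3 libraries were tested (25434 genes, 15314 of them protein-coding). Values were analysed as log2(TPM + 1), a scale on which changes of genes with few TPM are understated.

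In limma 3.58.1 (R 4.3.3) 1 linear model with a mean per group was fitted to all 30 libraries, with moderated variances and a trend on mean expression. The 18 comparisons were 8 of a drug with saline of the same day, 6 of CVAD with a single drug, 3 differences between days and 1 of saline on day 8 with day 2. P-values were 2-sided and adjusted by the Benjamini-Hochberg method over genes within each comparison, with a threshold of 0.05. The 31 gene lists were tested by camera in limma with a preset correlation of 0.01, adjusted over the 31 lists. The model shares 1 variance per gene over all groups, and p-values come from it even though each group has 3 libraries. Of the lists' members, 26 fell below the filter, 9 of these at 0 in every library, and Ahsp and Junb were not analysed. The lists name cell types and responses by usual markers, several of which ganglion cells also express.

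Genes were named by a rule. Against saline these are, among called genes whose groups did not overlap, the 8 largest in each direction leaving out predicted models, the 4 members of smallest p in each list that passed, and the 3 genes of smallest p where fewer than 5 passed. In the other comparisons the 4 largest in each direction were taken, and Fkbp5, Tsc22d3, Cdkn1a, Atf3 and Mki67 were checked throughout. The text gives a part of these. Predicted models and unnamed genes, Calca and Trpv1 were chosen after their values were seen.

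The comparisons, the lists, the rule and these alternatives were set before the data were examined: a pseudocount of 0.1, no filter, median-ratio scaling, a separate model for each day, library quality weights, an estimated correlation for the lists, and the omission of each library in turn. An alternative meant for count data was not run, because the table holds TPM. Added after the data were seen were protein-coding genes alone, a term for libraries 1 to 8, scores of spinal cord and muscle genes as covariates, and the omission of libraries for the list tests and marker sets. The similarity of single drugs and CVAD was compared with 100 simulations with no drug effect. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6. On simulated data of CVAD against saline on day 8 the pipeline called 8 of 25221 unchanged genes and 0 of 30 unchanged lists. It recovered a lowered list of 13 genes. Lists whose genes vary together were not simulated.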

Results

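Lumbar dorsal root ganglia hold the cell bodies of the sensory neurons of the hindlimb, with their satellite glia, Schwann cells, vessels and resident immune cells. Male C57BL/6J mice received saline, cyclophosphamide, vincristine, doxorubicin, dexamethasone, or CVAD, the combination of these 4 drugs. Ganglia L3 to L5 were taken from both sides on day 2 or day 8. The 30 libraries form 10 groups of 3. Day 2 has CVAD, cyclophosphamide, dexamethasone and saline, and day 8 has these 4 with vincristine and doxorubicin. Below, TPM (transcripts per 1e+06) values are means ± SD of 3 libraries, log2 fold changes carry their SE, and a gene with a library listed at 0 is given library by library.

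The table gives TPM for 56686 genes. Between 25342 and 27972 genes were above 0 in each library, and 25434 genes passed the filter on expression and were tested. Protein-coding genes carried 60.5 to 73.8% of the TPM. Genes of the misc_RNA type carried 13.4 to 28.3%, of which Rn7s2, an RNA of the signal recognition particle, held 7.08 to 16.4%. The most abundant coding gene was Ubb, a ubiquitin gene, at a mean of 1296 TPM. All 37 mitochondrial genes were listed at 0 in every library. Pairs of libraries correlated at r = 0.956 to 0.973, with a median of 0.966 within groups and 0.966 between groups.

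Lists of genes for 31 cell types and responses were fixed before the data were examined. A list that passed with the preset correlation between its genes is said to have risen or fallen, relative to the other tested genes. The median over all genes was 0.0691 in CVAD on day 2. With a correlation estimated from the data 2 calls held, both of the neutrophil list on day 8: CVAD against saline and against dexamethasone. All other list calls below were lost. The p-values of single genes measure only the spread between samples, and the labels do not say whether each is 1 animal or a pool. Those of lists with the preset correlation set list genes against the other genes. They do not measure how far the mean of a list varies between libraries. For the neutrophil list in CVAD on day 8 that mean was −1.436 with an SE between libraries of 0.336.

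CVAD was compared with saline on day 8. Genes of neutrophil granules were lower. Camp (ENSMUSG00000038357, chromosome 9), which encodes cathelicidin, was at 8.88 ± 0.238 TPM in CVAD and 38.01 ± 8.95 in saline, with a log2 fold change of −1.95 ± 0.35 and an adjusted p of 0.0944. Ngp (ENSMUSG00000032484, chromosome 9), the neutrophilic granule protein, was at 34.3 ± 9.12 and 103.3 ± 16.7 TPM (log2 fold change −1.58 ± 0.29, adjusted p = 0.0944). Elane (ENSMUSG00000020125, chromosome 10), neutrophil elastase, was at 3.70 ± 1.58 and 19.8 ± 6.998 TPM (log2 fold change −2.15 ± 0.40, adjusted p = 0.0944). Mpo (ENSMUSG00000009350, chromosome 11), myeloperoxidase, had a log2 fold change of −1.90 ± 0.41 and an adjusted p of 0.185. The neutrophil list fell, with all 13 tested genes lower and a mean log2 fold change of −1.44 (adjusted p = 1.43e-29; adjusted p = 0.0229 with an estimated correlation). Adjusted over the list alone 13 of its genes passed, and adjusted over all genes 0 did. S100a8 and S100a9, abundant neutrophil genes of this list, were at 0 in every library and not tested. The mean of the list was lower in each of the 3 CVAD libraries than in each of the 3 saline libraries, where the exact permutation test cannot give a p under 0.1. The call held when any 1 of the 6 libraries was left out.

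**Figure D1:**
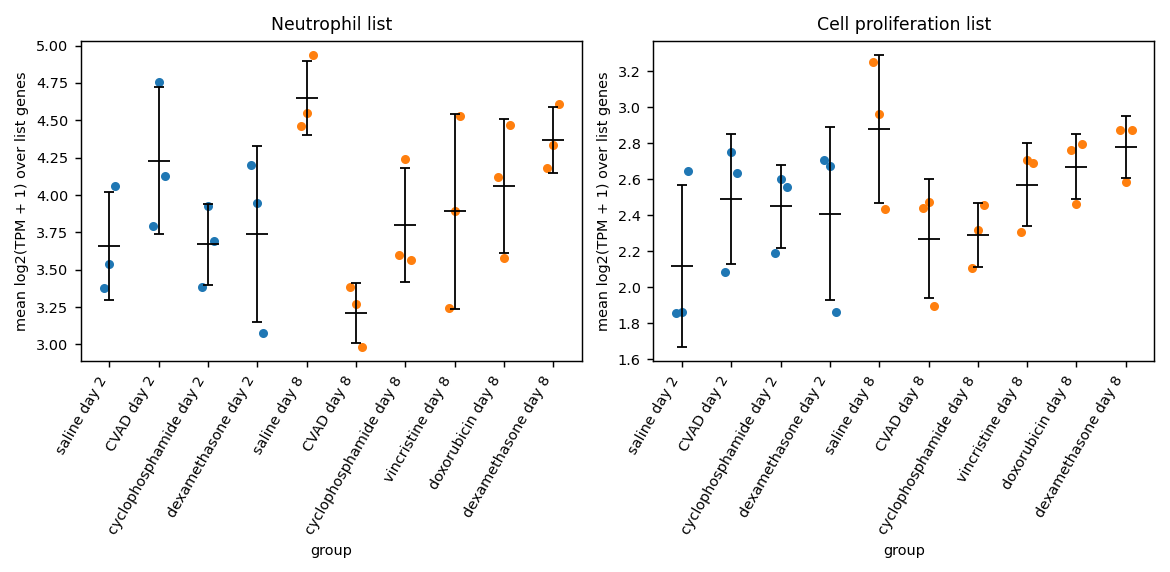
Mean log2(TPM + 1) over the genes of the neutrophil list (left) and of the cell proliferation list (right), for each of the 10 groups; points are the 3 libraries of a group (blue, day 2; orange, day 8), and bars are the group mean ± SD. On day 8 the neutrophil mean was 3.21 ± 0.20 in CVAD and 4.65 ± 0.25 in saline, and the cell proliferation mean 2.27 ± 0.33 and 2.88 ± 0.41.

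Genes of cell division and of lymphocytes were also lower in CVAD than in saline on day 8, in lists with adjusted p-values of 0.308 to 0.478 with an estimated correlation. The cell proliferation list fell, with 31 of 32 genes lower and a mean log2 fold change of −0.61 (adjusted p = 1.77e-15). Kif11, a spindle motor, was at 3.82 TPM against 7.21, Ccnb1 (cyclin B1) at 1.39 ± 0.396 against 5.17 ± 2.19, and Mki67, a marker of dividing cells, at 4.94 ± 2.74 against 13.8 ± 6.45. The T and NK cell list fell, with 8 of 9 genes lower and a mean of −0.55 (adjusted p = 0.00363). Lck, a kinase of T cell receptor signalling, was at 2.74 ± 0.489 TPM against 4.59 ± 1.30. Nkg7, a gene of cytotoxic granules, was listed at 0 in the 3 CVAD libraries and at 0, 3.46 and 5.30 TPM in saline. The B cell list fell, with all 12 genes lower and a mean of −0.69 (adjusted p = 0.000121). Igkc, the kappa light chain, was at 10.7 ± 7.27 TPM against 31.4 ± 15.2. No gene of these 3 lists passed over its list alone. The B cell mean was −0.41 without CVAD replicate 3 and −1.09 without saline replicate 3, and the call ended at −0.36 without saline replicate 2.

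Glucocorticoid target genes and genes of the response to nerve injury were higher in CVAD on day 8, in lists with an adjusted p of 0.478 with an estimated correlation. The glucocorticoid response list rose, with 19 of 21 genes higher, 2 of them past the threshold over the list alone, and a mean of 0.37 (adjusted p = 1.12e-05). The metallothionein genes Mt2 and Mt1 were at 82.3 ± 20.03 TPM against 38.8 ± 8.46 and at 99.2 ± 10.6 against 75.1 ± 11.3. Sgk1, a kinase induced by corticosteroids, was at 58.8 ± 18.6 against 38.2 ± 6.87, and Fkbp5, a co-chaperone of the glucocorticoid receptor, at 84.1 ± 23.8 against 60.7 ± 14.8. The mean was 0.21 without CVAD replicate 1 and 0.59 without CVAD replicate 3. The nerve injury response list rose, with 17 of 20 genes higher, 0 past the threshold over the list alone and a mean of 0.26 (adjusted p = 0.00175). Gal, the neuropeptide galanin, was at 55.5 ± 6.34 TPM against 39.5 ± 4.78, and Atf3, a transcription factor of injured neurons, at 22.8 ± 10.7 against 15.4 ± 5.59. The mean of this list was 0.40 without CVAD replicate 1 and 0.098 without saline replicate 2, and the call ended at 0.091 without CVAD replicate 2.

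A further 3 lists rose in CVAD on day 8, with adjusted p-values of 0.478 to 0.748 with an estimated correlation. The circadian clock list rose by 0.23 with 12 of 13 genes higher, 1 over the list alone (adjusted p = 0.00739), and Per2, a repressor of the clock, was at 18.5 ± 1.85 TPM against 10.9 ± 3.68. The list of endoplasmic reticulum and integrated stress rose by 0.12 with 11 of 14 higher, 1 over the list alone (adjusted p = 0.00862). The myelinating Schwann cell list rose by 0.21 with 13 of 14 higher (adjusted p = 0.0158). The clock mean ran from 0.048 to 0.38 with 1 library left out, and its call ended without saline replicate 2. The stress call ended without CVAD replicate 2 (0.077), saline replicate 1 (0.12) or saline replicate 3 (0.12). The Schwann cell mean ran from 0.11 to 0.38, and its call ended without CVAD replicate 2 or saline replicate 3.

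Another 7 lists fell in CVAD on day 8, with adjusted p-values of 0.478 to 0.777 with an estimated correlation. The adipocyte list fell with 7 of 8 genes lower, 2 over the list alone, and a mean of −0.64 (adjusted p = 0.000121), and Adipoq, the hormone adiponectin, was at 6.03 ± 2.79 TPM against 14.4 ± 3.06. Its mean was −0.37 without CVAD replicate 3. The other 6 calls ended or turned without CVAD replicate 3, and some without other libraries (ranges: 1 library left out). The bone and cartilage list was at −0.46 (−0.66 to −0.13, adjusted p = 0.00749), ending also without saline replicate 2. The interferon response list was at −0.13 (−0.20 to 0.006, adjusted p = 0.0137), turning without saline replicate 1. The macrophage list was at −0.097 (−0.26 to 0.029, adjusted p = 0.0251), ending without saline replicate 1 or 3. The mural cell list was at −0.10 (−0.21 to 0.051, adjusted p = 0.0206), ending without saline replicate 2 or 3. The cholesterol synthesis list was at −0.083 (−0.15 to 0.022, adjusted p = 0.0206), ending without saline replicate 1 or 2. The mitochondrial respiratory chain list was at −0.060 (−0.11 to 0.021, adjusted p = 0.0292), turning relative to the other genes without saline replicate 2.

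Over all genes, limma called 0 genes between CVAD and saline on day 8, and 1522 had an unadjusted p under 0.05. The count was 6 after median-ratio scaling, 4 with library quality weights, 4 with a separate model for each day, 2 with no filter, 7 among protein-coding genes alone, and 10 with a term for libraries 1 to 8 (described with day 2), these 2 chosen after the data were seen. With that term Camp, Ngp, Elane, Cd177 and Rac2 fell and Hspa1b, an inducible chaperone, rose. Elane, Ngp, Camp, Cd177 and Pirb were called under both median-ratio scaling and the restriction to coding genes. Without CVAD replicate 1 the count was 2, and without saline replicate 2 or 3 it was 1 or 3. In simulated data of this comparison the same test recovered 32.8% of 67 genes changed 1.5-fold, 65.7% of 67 changed 2-fold and 87.9% of 66 changed 4-fold.

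The lists of sensory neurons did not pass in any comparison with saline. In CVAD on day 8 the mean log2 fold change was −0.020 for the nociceptor list, 0.001 for the large-diameter neuron list and 0.016 for the list of pain-related ion channels. Calca, the precursor of the peptide CGRP, was at 264.6 ± 32.2 TPM in CVAD and 271.1 ± 28.1 in saline, and Trpv1, the capsaicin receptor, at 86.2 ± 12.2 and 91.6 ± 2.50 (these 2 genes were chosen after their values were seen). The lists of satellite glia (0.097), repair Schwann cells (0.029), fibroblasts and matrix (0.096) and cytokines and chemokines (−0.25) did not pass against saline either. The smallest adjusted p among these 7 lists in the 8 comparisons with saline was 0.0521, for the nociceptor list in CVAD on day 2. A p above the threshold does not show that values were equal.

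**Figure D2:**
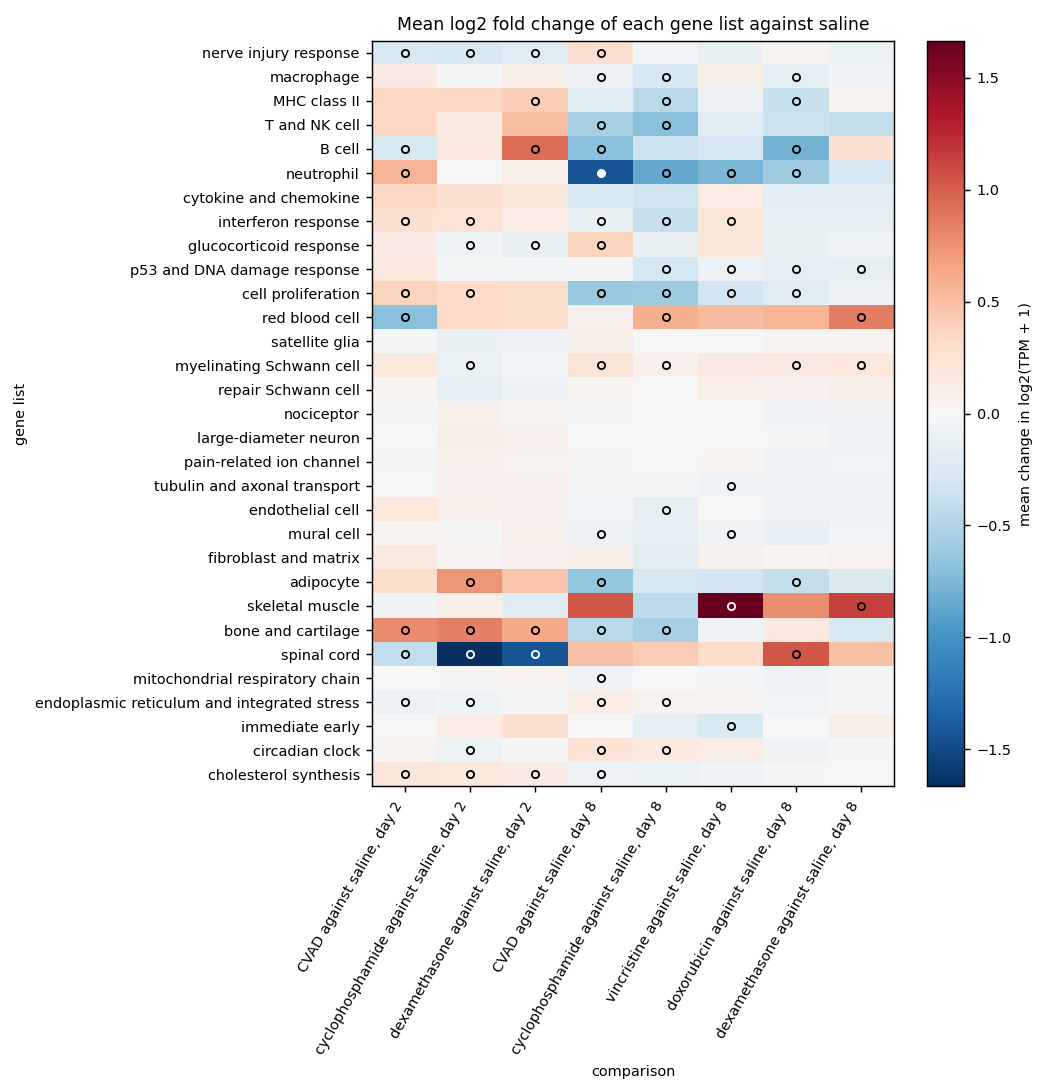
Mean log2 fold change of 31 gene lists (vertical axis) in the 8 comparisons with saline (horizontal axis), in units of log2(TPM + 1); red is higher than in saline and blue is lower. Open circles are lists past an adjusted p of 0.05 with the preset correlation of 0.01, and the filled circle, the neutrophil list in CVAD on day 8 at −1.44, also passed with an estimated correlation.

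Cyclophosphamide alone was compared with saline on day 8, when 2 genes and 9 lists fell and 4 lists rose. Gm13340, an unprocessed pseudogene on chromosome 2 (22478115 to 22479659), was at 70.1 ± 1.57 TPM in cyclophosphamide and 104.2 ± 10.3 in saline (log2 fold change −0.56 ± 0.082, adjusted p = 0.00974). Gm21104, a transcribed unprocessed pseudogene on chromosome 4 (42070757 to 42072779), was at 0.571, 0 and 1.18 TPM against 5.02, 2.90 and 5.58 (adjusted p = 0.0242). The neutrophil list fell with all 13 genes lower, 9 of them over the list alone, and a mean of −0.85 (adjusted p = 1.05e-09). Mpo was at 10.3 ± 4.16 TPM against 27.4 ± 12.03, and Ngp at 56.1 ± 9.34 against 103.3 ± 16.7. The cell proliferation list fell with 30 of 32 genes lower and a mean of −0.59 (adjusted p = 1.05e-09), and Bub1b, a spindle checkpoint kinase, was at 5.57 ± 3.14 TPM against 10.6 ± 1.31. For both lists the adjusted p = 0.482 with an estimated correlation, and both calls held when any 1 library was left out. Gm13340 lost its call without cyclophosphamide replicate 1 (−0.55) or saline replicate 1 (−0.48), and Gm21104 without cyclophosphamide replicate 1 (−1.86) or 2 (−1.54) or saline replicate 1 (−1.75) or 3 (−1.68).

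Genes of interferon responses, macrophages and antigen presentation were lower with cyclophosphamide on day 8, in lists with adjusted p-values of 0.482 to 0.613 with an estimated correlation. The interferon response list fell with 20 of 20 genes lower, 4 over the list alone, and a mean of −0.38 (adjusted p = 2.23e-08). The guanylate-binding protein genes Gbp2 and Gbp3 were at 14.8 ± 2.26 TPM against 30.7 ± 14.4 and at 9.29 ± 3.02 against 18.3 ± 5.30. The macrophage list fell with 18 of 20 genes lower, 1 over the list alone, and a mean of −0.27 (adjusted p = 6.60e-05), and Ctss, the protease cathepsin S, was at 22.2 ± 3.94 TPM against 34.6 ± 2.34. The MHC class II list fell with 8 of 8 genes lower and a mean of −0.46 (adjusted p = 0.00401), and H2-Ab1, a class II chain, was at 53.05 ± 17.3 TPM against 87.2 ± 22.9. The T and NK cell list fell with 8 of 9 lower and a mean of −0.69 (adjusted p = 0.00939), and the chemokine Ccl5 was listed at 0 in all 3 cyclophosphamide libraries and at 4.52, 0 and 5.35 TPM in saline. The interferon mean was −0.25 without saline replicate 1, and the macrophage mean −0.18 without cyclophosphamide replicate 1 and −0.44 without saline replicate 2. The MHC class II mean ran from −0.72 to −0.25 with 1 library left out, and its call ended without cyclophosphamide replicate 1 or saline replicate 1 or 2. The T and NK cell call ended at −0.54 without cyclophosphamide replicate 3.

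The p53 and DNA damage response list also fell with cyclophosphamide on day 8, with 21 of 22 genes lower, 1 over the list alone, and a mean of −0.29 (adjusted p = 5.93e-05; adjusted p = 0.594 with an estimated correlation). Gtse1, a p53-linked gene of the G2 phase, was at 1.61, 1.95 and 0 TPM against 4.29, 3.47 and 4.91, and Cdkn1a, the cell cycle inhibitor p21, had a log2 fold change of −0.042 ± 0.16. The call ended at −0.14 without saline replicate 3. Of the other 6 lists, whose adjusted p-values were 0.482 to 0.795 with an estimated correlation, each lost its call without at least 1 library (ranges: 1 library left out). The endothelial list fell by 0.16 (−0.25 to −0.080, adjusted p = 0.0180), ending without cyclophosphamide replicate 1 or 3 or saline replicate 1. The bone list fell by 0.56 (−0.66 to −0.43, adjusted p = 0.0301), ending without cyclophosphamide replicate 1 or saline replicate 2. The circadian clock list rose by 0.16 (−0.024 to 0.31, adjusted p = 0.00401), ending without cyclophosphamide replicate 2 and turning without saline replicate 2. The endoplasmic reticulum list rose by 0.064 (0.050 to 0.092, adjusted p = 0.0137), ending without cyclophosphamide replicate 1 or saline replicate 1 or 3. The red blood cell list rose by 0.60 (−0.62 to 1.38, adjusted p = 0.0240), ending without cyclophosphamide replicate 2 and turning without saline replicate 3. The myelinating Schwann cell list rose by 0.089 (−0.062 to 0.28, adjusted p = 0.0240), ending without cyclophosphamide replicate 2 and turning without cyclophosphamide replicate 3 or saline replicate 3. Besides the 2 genes that limma called, 1465 had an unadjusted p under 0.05, of which 20.6% were higher, or 39% after median-ratio scaling. The count was 0 without cyclophosphamide replicate 1 or saline replicate 1 and 4 without saline replicate 2 or 3.

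Vincristine, which binds tubulin, was compared with saline on day 8. The neutrophil list fell with 13 of 13 genes lower, 3 over the list alone, and a mean of −0.76 (adjusted p = 1.11e-13; adjusted p = 0.427 with an estimated correlation). Elane was at 6.18 ± 3.13 TPM against 19.8 ± 6.998, and Camp at 20.1 ± 9.88 against 38.01 ± 8.95. The cell proliferation list fell with 30 of 32 genes lower and a mean of −0.31 (adjusted p = 3.17e-06; adjusted p = 0.938 with an estimated correlation), and Ccnb1 was at 2.52 TPM against 5.17 ± 2.19. The immediate early list fell with 9 of 10 genes lower and a mean of −0.25 (adjusted p = 0.00345; adjusted p = 0.655 with an estimated correlation). The tubulin and axonal transport list fell with 16 of 19 genes lower and a mean of −0.055 (adjusted p = 0.0484; adjusted p = 0.938 with an estimated correlation). Its member Tuba1a, an alpha tubulin, was at 1084 ± 36.99 TPM against 997.8 ± 29.7. Tuba1a and its near relatives Tuba1b and Tuba1c averaged 1017, 870 and 867 TPM over all libraries, and whether reads were shared among them was not tested. The neutrophil mean was −0.44 and the proliferation mean −0.18 without vincristine replicate 1, and the latter was −0.13 and −0.54 without saline replicates 1 and 3. The immediate early call ended at −0.18 without saline replicate 2. The tubulin mean ran from −0.13 to 0.001 with 1 library left out, turning without vincristine replicate 2 or, relative to the other genes, without saline replicate 2.

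Interferon and muscle genes were higher with vincristine, in lists whose adjusted p = 0.938 with an estimated correlation. The interferon response list rose with 15 of 20 genes higher and a mean of 0.20 (adjusted p = 0.0126), and Mx2 and Ifi44, which interferon induces, were at 12.97 TPM against 8.50 and at 6.55 against 3.56. Its mean ran from 0.12 to 0.34 with 1 library left out, ending without vincristine replicate 1 or saline replicate 3. The skeletal muscle list rose with 12 of 12 genes higher and a mean of 1.67 (adjusted p = 0.00345). Ckm, muscle creatine kinase, was at 78.8, 78.2 and 33.7 TPM in vincristine and at 0, 50.4 and 25.5 in saline. The muscle call ended without saline replicate 1 (0.46) or vincristine replicate 1 (1.65) or 2 (1.19). The mural cell list fell by 0.080 (−0.15 to −0.019 with 1 library left out, adjusted p = 0.00784; adjusted p = 0.80 with an estimated correlation), ending without saline replicate 3. The p53 list fell by 0.10 (−0.21 to 0.050, adjusted p = 0.0454; adjusted p = 0.938 with an estimated correlation), ending without vincristine replicate 1 or 2 and turning without saline replicate 3. In limma 0 genes passed and 876 had an unadjusted p under 0.05. The smallest adjusted p was 0.125, of Gm13913, at 1.25, 2.04 and 1.55 TPM in vincristine and listed at 0 in saline. The count was 2 without saline replicate 2 or vincristine replicate 2, 7 without saline replicate 3 and 2 with no filter.

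With doxorubicin on day 8, 7 lists fell and 2 rose, each with an adjusted p of 0.738 with an estimated correlation. The neutrophil list fell with 13 of 13 genes lower, 0 over the list alone, and a mean of −0.59 (adjusted p = 1.99e-06), and its mean was −0.35 without doxorubicin replicate 2. Elane was at 8.07 ± 3.04 TPM against 19.8 ± 6.998. All day 8 drugs share these saline libraries, whose neutrophil level of 4.65 was the highest of the 10 groups. Only CVAD on day 8 (3.21) lay below saline on day 2 (3.66). The B cell list fell with 12 of 12 lower and a mean of −0.79 (adjusted p = 5.87e-05), and Igkc was at 9.67 ± 6.83 TPM against 31.4 ± 15.2. That call ended without doxorubicin replicate 1 (−0.64) or saline replicate 2 (−0.46). The spinal cord list rose with 8 of 8 genes higher and a mean of 1.04 (adjusted p = 1.26e-05), but the call ended at 0.17 without doxorubicin replicate 3. Slc6a5, the glycine transporter of inhibitory neurons, was at 0.487, 0 and 9.75 TPM in doxorubicin and 0.412, 0 and 0.142 in saline. The other 6 calls also ended or turned with single libraries (ranges: 1 library left out). The macrophage list fell by 0.15 (−0.31 to −0.046, adjusted p = 0.00297), ending without doxorubicin replicate 2 or saline replicate 3. The p53 list fell by 0.16 (−0.27 to −0.012, adjusted p = 0.0102), turning relative to the other genes without saline replicate 3. The MHC class II list fell by 0.37 (−0.60 to −0.13, adjusted p = 0.0272), ending without doxorubicin replicate 2 or saline replicate 1 or 2. The cell proliferation list fell by 0.21 (−0.43 to −0.025, adjusted p = 0.0288) and the adipocyte list by 0.39 (−0.78 to −0.12, adjusted p = 0.0316), both ending without doxorubicin replicate 1 or 2 or saline replicate 2, and also without saline replicate 1 and saline replicate 3, respectively. The myelinating Schwann cell list rose by 0.15 (0.016 to 0.32, adjusted p = 0.0311), ending without doxorubicin replicate 1 or 3 or saline replicate 3. In limma 0 genes passed and 852 had an unadjusted p under 0.05. The count was 1 without doxorubicin replicate 3 or saline replicate 1, 2 and 4 without saline replicates 2 and 3, and 2 with no filter.

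With dexamethasone, a synthetic glucocorticoid, 3 lists rose and 1 fell on day 8, each with an adjusted p of 0.863 with an estimated correlation. The red blood cell list rose with 9 of 9 genes higher and a mean of 0.85 (adjusted p = 0.00984). Hbb-bt, a beta globin, was at 8.39, 5.64 and 6.09 TPM in dexamethasone and 10.7, 0 and 0 in saline. The myelinating Schwann cell list rose with 14 of 14 higher and a mean of 0.17 (adjusted p = 0.00984). The skeletal muscle list rose with 12 of 12 higher and a mean of 1.14 (adjusted p = 0.0193). The p53 list fell with 18 of 22 lower and a mean of −0.16 (adjusted p = 0.0202). Fkbp5 and Tsc22d3, both glucocorticoid targets, had log2 fold changes of −0.19 ± 0.26 and −0.14 ± 0.13, and the glucocorticoid response list did not pass. With 1 library left out the red cell mean ran from −0.37 to 1.64, ending without dexamethasone replicate 1 and turning without saline replicate 3. The Schwann cell mean ran from 0.050 to 0.35, ending without dexamethasone replicate 1 or 3 or saline replicate 3. The muscle mean ran from −0.069 to 2.25, ending without dexamethasone replicate 1 or 2 and turning without saline replicate 1. The p53 mean ran from −0.27 to −0.012, ending without dexamethasone replicate 2 and turning relative to the other genes without saline replicate 3. In limma 0 genes passed and 830 had an unadjusted p under 0.05 (38.4% higher, 48.5% after median-ratio scaling). The smallest adjusted p, 0.072, was of ENSMUSG00000115420, at 9.12 ± 0.50 TPM against 0.217 ± 0.158. The count was 1 without dexamethasone replicate 3, 3 without saline replicate 3, and 1 with a pseudocount of 0.1, with no filter or with a separate model for each day.

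The libraries of day 2 differed in a feature that follows the library number given by the submitters. Libraries 1 to 8 hold all of CVAD and cyclophosphamide on day 2 and replicates 1 and 2 of dexamethasone, and the day 2 saline libraries all lie outside. In libraries 1 to 8 the genes of the rRNA type held 0.0471 to 0.112% of the TPM, and in the other 22 libraries 0.025 to 0.0458%. ENSMUSG00002076451, of the miRNA type on chromosome 12 (69206211 to 69206280), was at 64.1 to 107 TPM in libraries 1 to 8 and 1.07 to 45.1 TPM in the others. Among the others it was raised in libraries 24 to 27 and 30, at 19.4 to 45.1 TPM, which include all 3 dexamethasone libraries of day 8, and at 8.44 TPM or less in the rest. The rRNA type was not raised in those 5 libraries, at 0.035 to 0.039%. The numbering therefore separates CVAD and cyclophosphamide from saline on day 2. A term for libraries 1 to 8, added after the data were seen, rests on the dexamethasone libraries of day 2 and is given beside the values of that day.

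**Figure D3:**
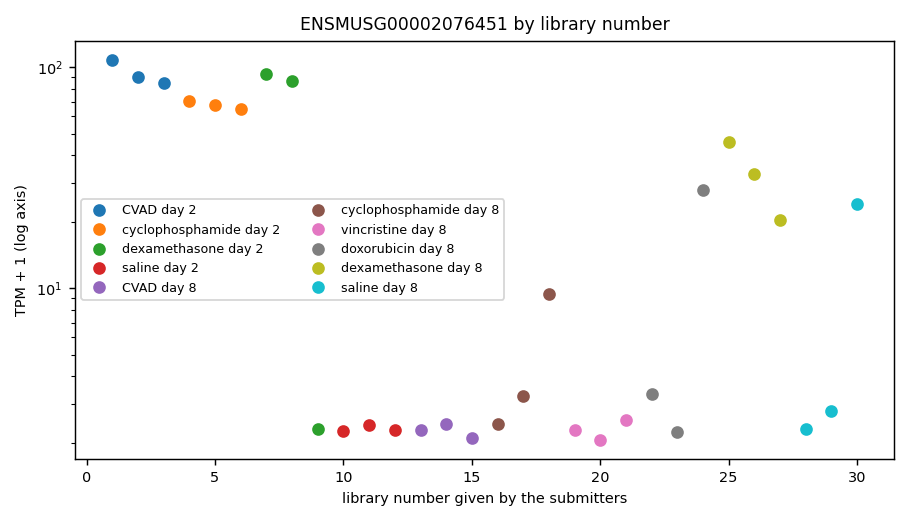
Level of ENSMUSG00002076451 in TPM + 1 on a log axis (vertical) against the library number given by the submitters (horizontal), with 1 point per library, coloured by group. Libraries 1 to 8 lie at 64.1 to 107 TPM and the others at 1.07 to 45.1 TPM.

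On day 2, 10 genes rose and 1 fell with CVAD relative to saline. Rps23, a protein of the small ribosomal subunit on chromosome 13 (91071077 to 91073069), was at 120.3 ± 10.99 TPM in CVAD and 88.9 ± 7.02 in saline (log2 fold change 0.43 ± 0.080, adjusted p = 0.0443). Zfp90, a zinc finger protein on chromosome 8 (107141959 to 107153230), was at 20.9 ± 0.842 and 14.97 ± 0.722 TPM (log2 fold change 0.46 ± 0.084, adjusted p = 0.0443). Of the other 8 genes that rose, 3 were the processed pseudogenes Gm5561, Gm48088 and Gm5539, at 49.03, 49.6 and 54.02 TPM in CVAD against 25.2, 25.06 and 34.98, and 5 were unnamed genes of the miRNA type, among them ENSMUSG00002076451 at 93.6 ± 12.1 against 1.32 ± 0.0844 TPM. The gene that fell, ENSMUSG00002075948 of the misc_RNA type, was listed at 0 in the 3 CVAD libraries and was at 1.22, 1.34 and 1.19 TPM in saline (adjusted p = 0.00634). After median-ratio scaling 11 genes were higher and 3 lower. Of 2084 genes with an unadjusted p under 0.05, 85.1% were higher in CVAD, and 55.9% after that scaling. The count was 0 without CVAD replicate 1 or 2 or saline replicate 1 or 2, 4 without CVAD replicate 3 and 2 without saline replicate 3. It was 98 with quality weights, 4 with covariates, 2 with no filter, 1 with separate days and 0 among coding genes alone. With the term for libraries 1 to 8 it was 2, Map4k1 and AU022252, neither of them among the 11.

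Among the lists, 10 passed in CVAD on day 2, each with an adjusted p of 0.814 with an estimated correlation. The nerve injury response list fell with 14 of 20 genes lower and a mean of −0.25 (adjusted p = 0.000153), and Atf3 was at 10.97 ± 3.31 TPM against 18.9 ± 7.45. The list of endoplasmic reticulum and integrated stress fell by 0.092 with 12 of 14 lower (adjusted p = 0.000153). Without saline replicate 3 these means were −0.071 and −0.034. The neutrophil list rose with 13 of 13 higher and a mean of 0.57 (adjusted p = 0.00271), and Camp was at 26.2 ± 8.53 TPM against 12.6 ± 4.81. Its call ended at 0.30 without CVAD replicate 2. The bone and cartilage list rose with 9 of 9 higher, 2 over the list alone, and a mean of 0.78 (adjusted p = 0.00277). Mmp13, a collagenase of cartilage and bone, was at 16.5 ± 7.53 TPM against 3.24 ± 3.15, and the call ended without CVAD replicate 3 (0.60) or saline replicate 2 (0.59) and was 1.21 without saline replicate 3. With the term for libraries 1 to 8 the mean turned to −0.42 for the neutrophil list and 0.002 for the endoplasmic reticulum list. These shifts rest on dexamethasone replicate 3 as the only outside library of its group.

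The other 6 calls in CVAD on day 2 ended or turned with single libraries (ranges: 1 library left out). The cholesterol synthesis list rose by 0.19 (0.13 to 0.28, adjusted p = 0.00327), ending without CVAD replicate 2 or 3 or saline replicate 2. The interferon list rose by 0.25 (0.14 to 0.47, adjusted p = 0.0146), ending without CVAD replicate 3 or saline replicate 1 or 2, and the cell proliferation list by 0.36 (0.23 to 0.63, adjusted p = 0.0233), ending without those 3 or CVAD replicate 2. The red blood cell list fell by 0.69 (−1.49 to 0.23, adjusted p = 0.0214), turning without CVAD replicate 1 and ending without saline replicate 2. The spinal cord list fell by 0.41 (−0.96 to −0.022, adjusted p = 0.0214), ending without CVAD replicate 2 or saline replicate 2 or 3. The B cell list fell by 0.25 (−0.31 to −0.15, adjusted p = 0.0233), ending without CVAD replicate 1 or 2 or saline replicate 1 or 2. With the term for libraries 1 to 8 the mean turned to −0.099 for interferon, −0.46 for proliferation and 0.23 for spinal cord.

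Genes of the spinal cord were lower with cyclophosphamide than with saline on day 2. The spinal cord list fell with 8 of 8 genes lower, 5 over the list alone, and a mean of −1.67 (adjusted p = 1.78e-10; adjusted p = 0.357 with an estimated correlation), and its call held when any 1 library was left out. Slc1a2, an astrocyte glutamate transporter, was at 3.95 ± 1.49 TPM against 22.4 ± 17, and Mog, a myelin protein of the central nervous system, at 0, 0 and 0.608 against 1.93, 7.18 and 8.89. Of single genes, Gm50451, a snoRNA on chromosome 5 (23915989 to 23916059), was at 5.13, 3.67 and 4.34 TPM and listed at 0 in the 3 saline libraries (adjusted p = 0.0171). Gm22516, a snoRNA on chromosome 2 (31079703 to 31079826), was at 0.744, 1.75 and 0 TPM against 7.90, 7.78 and 7.48 (adjusted p = 0.0230). ENSMUSG00002075948 was listed at 0 in the 3 libraries (adjusted p = 0.00634). In limma these 3 passed, 1909 genes had an unadjusted p under 0.05, and 79.6% of those were higher, or 52.3% after median-ratio scaling. The count was 0 without cyclophosphamide replicate 1 or 3 or saline replicate 1 or 2, and 1 without saline replicate 3. It was 50 with quality weights and 0 with a pseudocount of 0.1, coding genes alone or covariates.

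A further 10 lists passed for cyclophosphamide on day 2, with adjusted p-values of 0.898 to 0.966 with an estimated correlation. The nerve injury response list fell by 0.26 with 14 of 20 genes lower (adjusted p = 0.000404). This call held, at −0.081 without saline replicate 3. The other 9 ended or turned with single libraries (ranges: 1 library left out). The bone list rose by 0.84 (0.59 to 1.27, adjusted p = 0.00293), ending without saline replicate 2, and the adipocyte list by 0.73 (0.49 to 0.96, adjusted p = 0.00482), ending without saline replicate 1. The cholesterol list rose by 0.17 (0.13 to 0.24, adjusted p = 0.00687), ending without cyclophosphamide replicate 1 or saline replicate 2. The interferon list rose by 0.25 (0.13 to 0.46, adjusted p = 0.0148), ending without cyclophosphamide replicate 1 or saline replicate 1 or 2, and the proliferation list by 0.33 (0.19 to 0.59, adjusted p = 0.0290), ending without cyclophosphamide replicate 2 or 3 or saline replicate 1 or 2. The myelinating Schwann cell list fell by 0.11 (−0.20 to −0.047, adjusted p = 0.00482), ending without cyclophosphamide replicate 2, and the endoplasmic reticulum list by 0.069 (−0.13 to −0.002, adjusted p = 0.00482), ending without cyclophosphamide replicate 3. The glucocorticoid list fell by 0.075 (−0.27 to 0.21, adjusted p = 0.0218), ending without cyclophosphamide replicate 2 and turning without saline replicate 3. The clock list fell by 0.087 (−0.14 to −0.047, adjusted p = 0.0290), ending without cyclophosphamide replicate 1 or 2 or saline replicate 1 or 2. With the term for libraries 1 to 8 the mean turned to −0.11 for interferon, −0.50 for proliferation, 0.043 for Schwann cells, 0.025 for endoplasmic reticulum stress and 0.026 for the clock.

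With dexamethasone on day 2 the glucocorticoid response list fell relative to saline. Its mean was −0.13, with 16 of 21 genes lower (adjusted p = 0.00352; adjusted p = 0.995 with an estimated correlation). Mt2 was at 41.1 TPM against 61.4 ± 22.1, and Fkbp5 at 50.7 ± 6.90 in dexamethasone and at 45.5, 49.8 and 96.5 in the 3 saline libraries. Without saline replicate 3 the mean turned to 0.16, and with another library left out it ran down to −0.32. The spinal cord list fell with 8 of 8 genes lower, 2 over the list alone, and a mean of −1.44 (adjusted p = 1.34e-10; adjusted p = 0.344 with an estimated correlation). The B cell list rose with 11 of 12 higher and a mean of 0.94 (adjusted p = 0.00012; adjusted p = 0.995 with an estimated correlation), and Iglc2, a lambda light chain, was at 1.36, 3.77 and 2.28 TPM and listed at 0 in saline. The spinal cord and B cell calls held when any 1 library was left out.

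The other 4 lists that passed for dexamethasone on day 2 had an adjusted p of 0.995 with an estimated correlation (ranges: 1 library left out). The nerve injury list fell by 0.21 (−0.33 to −0.032, adjusted p = 0.00352), ending without saline replicate 3. The bone list rose by 0.64 (0.39 to 1.07, adjusted p = 0.0319), ending without dexamethasone replicate 1 or 3 or saline replicate 1 or 2. The MHC class II list rose by 0.40 (0.22 to 0.64, adjusted p = 0.0369), ending without dexamethasone replicate 1 or 2 or saline replicate 1 or 2, and H2-Ab1 was at 75.7 ± 27.5 TPM against 47.5 ± 12.4. Its mean turned to −0.063 with the term for libraries 1 to 8. The cholesterol list rose by 0.13 (0.092 to 0.20, adjusted p = 0.0421), ending without every library except saline replicate 3. In limma 1 gene passed, ENSMUSG00002075948, and 1365 had an unadjusted p under 0.05 (80.4% higher, 54.6% after median-ratio scaling). The count was 0 without dexamethasone replicate 1 or 2 or saline replicate 1 or 2, and 76, 65 of them higher, without dexamethasone replicate 3, the library outside the first 8.

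In the 8 comparisons with saline, none of the check genes Fkbp5, Tsc22d3, Cdkn1a, Atf3 and Mki67 passed. On day 8 the log2 fold change of Atf3 was 0.49 ± 0.33 in CVAD, 0.080 ± 0.33 in cyclophosphamide, −0.22 ± 0.33 in vincristine, −0.078 ± 0.33 in doxorubicin and −0.41 ± 0.33 in dexamethasone. On day 2 it was −0.70 ± 0.33, −0.96 ± 0.33 and −0.74 ± 0.33 in CVAD, cyclophosphamide and dexamethasone. Cdkn1a ranged from −0.18 ± 0.16 in cyclophosphamide on day 2 to 0.19 ± 0.16 in CVAD on day 2.

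CVAD was compared directly with each single drug on day 8. The neutrophil list was lower in CVAD in each of the 4 comparisons. Its mean log2 fold change was −1.16 against dexamethasone (13 of 13 genes lower, 12 over the list alone, adjusted p = 8.09e-26; adjusted p = 0.0423 with an estimated correlation) and −0.84 against doxorubicin (12 of 13 lower, 9 over the list alone, adjusted p = 1.36e-15; adjusted p = 0.225 with an estimated correlation). It was −0.67 against vincristine (13 of 13 lower, 3 over the list alone, adjusted p = 8.13e-10; adjusted p = 0.284 with an estimated correlation) and −0.59 against cyclophosphamide (11 of 13 lower, 3 over the list alone, adjusted p = 2.68e-11; adjusted p = 0.727 with an estimated correlation). The mean against vincristine was −0.35 without vincristine replicate 3, and that against cyclophosphamide −0.37 without cyclophosphamide replicate 2. Proliferation genes fell by 0.51 against dexamethasone (adjusted p = 1.03e-13), 0.41 against doxorubicin (adjusted p = 7.32e-10) and 0.30 against vincristine (adjusted p = 5.27e-05), with adjusted p-values of 0.340 to 0.678 with an estimated correlation. Without CVAD replicate 3 these 3 means were −0.32, −0.22 and −0.11. Against cyclophosphamide, where the median over all genes was 0.0638, it was −0.024 (−0.13 to 0.16 with 1 library left out, adjusted p = 0.0449; adjusted p = 0.867 with an estimated correlation). The call turned without replicate 3 of either group and ended without cyclophosphamide replicate 2.

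The glucocorticoid response list was higher in CVAD than in every single drug on day 8, with adjusted p-values of 0.297 to 0.835 with an estimated correlation. It rose by 0.49 against cyclophosphamide (21 of 21 genes, adjusted p = 2.74e-08), 0.49 against doxorubicin (21 of 21, 2 over the list alone, adjusted p = 7.32e-10), 0.44 against dexamethasone (19 of 21, 2 over the list alone, adjusted p = 8.77e-09) and 0.18 against vincristine (18 of 21, adjusted p = 0.00202). With 1 library left out the mean ran from 0.33 to 0.71, 0.34 to 0.71, 0.29 to 0.66 and 0.025 to 0.40, and against vincristine the call ended without CVAD replicate 1 or vincristine replicate 3. The following lists had adjusted p-values of 0.284 to 0.835 with an estimated correlation. The nerve injury list rose by 0.39 against vincristine (adjusted p = 2.79e-07) and by 0.37 against dexamethasone (adjusted p = 6.75e-06). The interferon list was lower in CVAD than in vincristine (−0.33, 20 of 20, adjusted p = 1.02e-08) and higher than in cyclophosphamide (0.25, 19 of 20, adjusted p = 0.00394). The fibroblast and matrix list rose by 0.27 against cyclophosphamide (adjusted p = 0.00347), and the cytokine and chemokine list fell by 0.38 against vincristine (adjusted p = 0.00391). In the comparisons between drugs, omission of single libraries was run for the neutrophil, proliferation and glucocorticoid lists alone. In all, 12 lists passed against cyclophosphamide, 12 against vincristine, 9 against doxorubicin and 12 against dexamethasone.

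No single gene passed between CVAD and a single drug on day 8 in limma. The counts at an unadjusted p under 0.05 were 1358 against cyclophosphamide (85% higher in CVAD, 56.8% after median-ratio scaling), 885 against vincristine, 1220 against doxorubicin (66.3% higher, 47.2% after scaling) and 1257 against dexamethasone (62.9% higher, 46.9% after scaling). Without CVAD replicate 1 the adjusted counts against cyclophosphamide, doxorubicin and dexamethasone were 1, 2 and 2. Against vincristine the count was 2 without CVAD replicate 2 and 1 without vincristine replicate 2. Against cyclophosphamide it was 3 without cyclophosphamide replicate 2, and against dexamethasone it was 1 without CVAD replicate 3 and 2 without dexamethasone replicate 3. None of the 5 check genes passed here or in the comparisons that follow.

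On day 2 CVAD was compared with cyclophosphamide and dexamethasone. The neutrophil list was higher in CVAD, by 0.56 against cyclophosphamide (13 of 13 genes, adjusted p = 1.17e-05; adjusted p = 0.805 with an estimated correlation) and by 0.48 against dexamethasone (adjusted p = 9.22e-05; adjusted p = 0.886 with an estimated correlation). Without CVAD replicate 2 these means were 0.29 and 0.22, and the call against dexamethasone ended at 0.15 without dexamethasone replicate 3. CVAD and cyclophosphamide both lie within libraries 1 to 8. Against cyclophosphamide the adjusted p-value of each list was 0.805 with an estimated correlation. The spinal cord list rose by 1.25 (8 of 8, adjusted p = 6.06e-05), the nociceptor list fell by 0.10 (19 of 19, adjusted p = 0.0037), the large-diameter neuron list by 0.11 (12 of 14, adjusted p = 0.00374) and the list of pain-related ion channels by 0.060 (22 of 26, adjusted p = 0.0037). Against dexamethasone the B cell list fell by 1.19 (12 of 12, 6 over the list alone, adjusted p = 4.62e-12; adjusted p = 0.437 with an estimated correlation) and the glucocorticoid list rose by 0.26 (19 of 21, adjusted p = 0.00308; adjusted p = 0.886 with an estimated correlation). The latter turned relative to the other genes, at 0.055, without CVAD replicate 1. In both comparisons 13 lists passed. In limma 1 gene passed against cyclophosphamide, Gm50451, listed at 0 in the 3 CVAD libraries (adjusted p = 0.0341), with 975 at an unadjusted p under 0.05. Against dexamethasone 0 genes passed, with 931 at an unadjusted p under 0.05. The count against cyclophosphamide was 0 without CVAD replicate 1 or 2 or cyclophosphamide replicate 1 or 3 and 2 without cyclophosphamide replicate 2, and that against dexamethasone 2 without CVAD replicate 3.

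The change of CVAD against saline between day 2 and day 8 was tested as an interaction, and 21 genes passed, 6 of them with a more positive and 15 with a more negative difference on day 8. Several neutrophil genes were among those that fell. The smallest adjusted p was of the processed pseudogene Gm4739 (−3.01 ± 0.44, adjusted p = 0.00894), and the largest fall of Fcnb, a ficolin of granulocytes, at −4.60 ± 0.92 (adjusted p = 0.0496). Camp had a difference of −2.96 ± 0.49 in log2 fold change (adjusted p = 0.0193), from 26.2 against 12.6 TPM on day 2 to 8.88 against 38.01 on day 8. Cd177, a surface protein of neutrophils on chromosome 7, had −2.91 ± 0.50 (adjusted p = 0.0193), from 13.97 against 6.22 TPM to 3.07 against 14.4. Elane had −2.92 ± 0.57 (adjusted p = 0.0444) and Ngp −2.25 ± 0.41 (adjusted p = 0.0283). Rac2, a GTPase of blood cells on chromosome 15, had −2.02 ± 0.34 (adjusted p = 0.0193). The inducible chaperone genes Hspa1a and Hspa1b rose, by 1.79 ± 0.32 (adjusted p = 0.0283) and 1.51 ± 0.26 (adjusted p = 0.0193). Hspa1a went from 20.1 ± 2.74 against 35.7 ± 8.29 TPM on day 2 to 42.97 ± 9.78 against 20.8 ± 3.70 on day 8. The neutrophil list fell with 13 of 13 genes lower, 3 past the threshold over all genes and 11 over the list alone, and a mean of −2.00 (adjusted p = 1.78e-20; adjusted p = 0.109 with an estimated correlation). The cell proliferation list fell with 30 of 32 lower, 12 over the list alone, and a mean of −0.98 (adjusted p = 2.43e-11; adjusted p = 0.356 with an estimated correlation).

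The saline groups enter this difference, and library numbers 1 to 8 hold the CVAD libraries of day 2. With the term for libraries 1 to 8 the count was 1, the genes named above lost their calls, the difference of Camp was −2.07, the neutrophil mean was −1.01 and the proliferation mean was −0.15. The count was 0 without CVAD day 8 replicate 3, 1 without CVAD day 2 replicate 2, CVAD day 8 replicate 2 or saline day 2 replicate 1, 2 without saline day 8 replicate 3, 6 without CVAD day 2 replicate 1 and 8 without saline day 2 replicate 2. It was 12 without CVAD day 2 replicate 3 and 13 without CVAD day 8 replicate 1 or saline day 8 replicate 2, and 86 with quality weights and 11 with no filter. Of 2195 genes with an unadjusted p under 0.05, 27.1% were more positive on day 8, and 41.9% after median-ratio scaling, when 36 genes passed, 9 of them more positive.

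For cyclophosphamide and dexamethasone the same differences between days gave 0 genes in limma, with 2430 and 1251 at an unadjusted p under 0.05. The interferon list fell for cyclophosphamide with 20 of 20 genes lower, 5 over the list alone, and a mean difference of −0.63 (adjusted p = 1.93e-07; adjusted p = 0.441 with an estimated correlation). Proliferation genes fell by 0.92 with 32 of 32 lower (adjusted p = 1.10e-07) and the neutrophil list by 0.86 with 13 of 13 lower (adjusted p = 0.00141), each with an adjusted p = 0.609 with an estimated correlation. With the term for libraries 1 to 8 these last 2 means were −0.089 and 0.14. The spinal cord list rose by 2.08 for cyclophosphamide (adjusted p = 3.19e-08; adjusted p = 0.441 with an estimated correlation) and by 1.93 for dexamethasone (adjusted p = 7.36e-09; adjusted p = 0.580 with an estimated correlation). For cyclophosphamide the median over all genes was −0.11, and 1e-04 after median-ratio scaling. Of its genes at an unadjusted p under 0.05, 15% were more positive, and 44.8% after scaling. For dexamethasone the shares were 21.7% and 47.4%. The count for cyclophosphamide was 42 with quality weights, 2 without cyclophosphamide day 2 replicate 1 or day 8 replicate 2 and 3 without saline day 2 replicate 3, and for dexamethasone it was 2 without dexamethasone day 8 replicate 3.

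The saline groups themselves differed between the days, in some of the same lists. From day 2 to day 8 the cell proliferation list rose with 31 of 32 genes higher, 15 over the list alone, and a mean of 0.76 (adjusted p = 1.95e-13; adjusted p = 0.410 with an estimated correlation). The neutrophil list rose with 13 of 13 higher, 9 over the list alone, and a mean of 0.99 (adjusted p = 4.32e-11; adjusted p = 0.409 with an estimated correlation). The interferon list rose by 0.39 with 20 of 20 higher, 4 over the list alone (adjusted p = 8.86e-07; adjusted p = 0.437 with an estimated correlation), and the spinal cord list fell by 1.65 with 8 of 8 lower, 5 over the list alone (adjusted p = 1.29e-10; adjusted p = 0.394 with an estimated correlation). In all 17 lists passed, 11 up and 6 down. In limma 1 gene passed, ENSMUSG00002075948, listed at 0 on day 8, and 1762 had an unadjusted p under 0.05 (79.8% higher on day 8, 54.8% after median-ratio scaling). The count was 0 without saline day 2 replicate 1 or 2 or saline day 8 replicate 1, 2 without saline day 2 replicate 3, and 3 and 5 without saline day 8 replicates 2 and 3.

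The changes of each single drug were set against those of CVAD over the 25434 tested genes. Because both use the same saline libraries, data simulated with no drug effect gave a correlation of 0.50 with an SD of 0.0102. On day 8 the observed correlation was r = 0.575 for cyclophosphamide, 0.566 for vincristine, 0.541 for doxorubicin and 0.506 for dexamethasone. On day 2 it was 0.561 for cyclophosphamide and 0.551 for dexamethasone. The simulation takes no account of genes that vary together, so its SD cannot show how unusual these values are. It also ignores libraries 1 to 8, so the day 2 values do not separate a shared batch from the drugs. With 3 saline libraries per day, the controls were too few to give each drug its own. Against saline of day 2, ENSMUSG00002075948 was called at −1.167 in CVAD and both drugs of that day and in saline of day 8. All were at 0 TPM, so the shared saline libraries fix this overlap.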

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

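All tests of explanations in this part were chosen after the results were seen. Several results were singled out because the effect of a drug differed between day 2 and day 8 in a test of that difference. In CVAD the count was 21 genes, the neutrophil mean −2.005 (adjusted p = 0.109 with an estimated correlation) and the cell proliferation mean −0.979 (adjusted p = 0.356 with an estimated correlation). In cyclophosphamide the neutrophil mean was −0.857 and the cell proliferation mean −0.916, each with an adjusted p of 0.609 with an estimated correlation. With a term for libraries 1 to 8 the CVAD count was 1, its neutrophil mean −1.01 and its proliferation mean −0.15, and the cyclophosphamide means were 0.14 and −0.089. Groups of 3 libraries are too small for the test for a single distant sample.

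The lower granulocyte genes in CVAD on day 8 (precursor genes at log2 −1.83 ± 0.36) were weighed against 2 technical explanations. A larger share of 7SL and 7SK RNA in the TPM total, which would lower all other genes alike, is argued against, since the value was −1.85 after median-ratio scaling and Rn7s2 held 9.81, 8.4 and 14.02% of the TPM in CVAD and 9.92, 11.5 and 10.3% in saline. Less bone marrow of every lineage carried over with the ganglia stays open for part or all of it. Erythroid precursor genes were at −0.596 ± 0.68, B cell precursors at −0.62 ± 0.28, megakaryocytes at −0.81 ± 0.27, bone at −0.46 ± 0.33 and red blood cells at 0.076 ± 0.785. Single libraries set the erythroid value, which was −1.64 without saline replicate 3, beside −1.62 for granulocyte precursors, but −0.006 without saline replicate 1, beside −2.05. A high day 8 saline group (precursors 1.28 ± 0.36 above day 2) may add to the fall. A drug effect on granulocyte number stays open, not tested apart from these.

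The 11 genes called in CVAD on day 2 were weighed against a technical batch of libraries 1 to 8. Of these, 9 differed in the same direction between dexamethasone replicates 1 and 2, inside those libraries, and replicate 3, outside, with a median difference of 0.78 against 1.17 in CVAD. Over all tested genes 63.1% did so (r = 0.15), and over genes with an unadjusted p under 0.05 81.3%. The outside arm is 1 library, with a neutrophil score of 3.08 against 4.2 and 3.94, so the batch is a weak candidate explanation that cannot be told apart from the drugs for CVAD and cyclophosphamide on day 2. An effect of CVAD on these genes stays open as well.

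Spinal cord genes were lower than saline in cyclophosphamide and dexamethasone on day 2. Spinal cord tissue dissected with some ganglia may be the source, as genes of cord inhibitory neurons and of oligodendrocytes correlated at r = 0.81 within groups over the 30 libraries. Without 2 of the libraries r was 0.77. An effect of the drugs was not tested apart from it.

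For each comparison the libraries were also split in other ways, with the count of called genes taken each time. For 3 libraries against 3 there are 10 splits, too few to give a share under 0.05, and those with at least as many genes as the real split, itself included, were counted. For CVAD, cyclophosphamide and dexamethasone against saline on day 2 they numbered 1, 1 and 3 (real 11, 3 and 1, highest others 1, 1 and 14). The split with 14 genes joins dexamethasone replicates 1 and 2 with saline replicate 3. It follows proliferation scores (2.71, 2.67 and 2.65 against 1.86 each), and libraries 1 to 8 only in part. On day 8 they numbered 2 for cyclophosphamide (real 2, highest other 2) and 10 for CVAD, vincristine, doxorubicin and dexamethasone (real 0, highest others 2, 1, 1 and 2). For CVAD against cyclophosphamide and dexamethasone on day 2 they numbered 4 and 10 (real 1 and 0, highest others 2 and 0). For CVAD against cyclophosphamide, vincristine, doxorubicin and dexamethasone on day 8 they numbered 10 each (real 0, highest others 2, 1, 2 and 1), and for saline between days 7 (real 1, highest other 2). Of 100 splits drawn for the differences between days, 1 gave as many as the real 21 in CVAD (highest other 2). This cannot decide on chance, because the real split follows libraries 1 to 8, which hold CVAD and not saline on day 2. The count was 1 with a term for them and 0 without CVAD day 8 replicate 3. For cyclophosphamide and dexamethasone all 100 gave as many as the real 0 (highest others 2 and 9).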

How the results depend on the processing

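The batch term (for libraries 1 to 8), covariates, coding genes alone and omissions for lists were chosen after the data were seen. The direction of the neutrophil list in CVAD on day 8 and its call were kept under every alternative run. Of the lists that passed against saline, 1 kept its call with an estimated correlation and 77 lost it. Among these and the neutrophil, proliferation and glucocorticoid calls elsewhere, those lost numbered 15 with the batch term, 16 with spinal cord and muscle covariates, 13 with quality weights, 11 with no filter, 7 with median-ratio scaling, 7 with coding genes alone, 3 with separate days and 2 with a pseudocount of 0.1. A further 12 reversed with the batch term, 6 with covariates, 1 of them by construction, and 3 with quality weights. With 1 library left out 487 stayed, 129 lost the call and 26 reversed. No paired analysis was possible because the replicate numbers only name samples within a group. The depth is unknown, so no result could be tied to it. Except where fewer genes or libraries were tested, the cause was not tested.

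Counts of called genes moved as follows. With a pseudocount of 0.1, cyclophosphamide day 2 went from 3 to 0, dexamethasone day 2 from 1 to 0, cyclophosphamide day 8 from 2 to 1, dexamethasone day 8 from 0 to 1, CVAD against cyclophosphamide on day 2 from 1 to 0, CVAD against doxorubicin and dexamethasone on day 8 from 0 to 1 and 2, dexamethasone between days from 0 to 1, and saline from 1 to 0. With no filter, CVAD gave 2 on day 2 and 2 on day 8, cyclophosphamide, vincristine, doxorubicin and dexamethasone on day 8 gave 5, 2, 2 and 1, CVAD against cyclophosphamide and dexamethasone on day 2 gave 6 and 6, against cyclophosphamide, vincristine, doxorubicin and dexamethasone on day 8 1, 4, 2 and 1, the differences between days 11 (CVAD), 2 and 2, and saline 2. Median-ratio scaling gave 6 for CVAD day 8 and 36 for CVAD between days. Separate days gave 1 for CVAD day 2, 4 for CVAD day 8, 1 for dexamethasone day 8 and 1 for CVAD against dexamethasone on day 8. Quality weights gave 98 for CVAD day 2, 50 for cyclophosphamide day 2, 4 for CVAD day 8, 0 for CVAD against cyclophosphamide on day 2, 2 against doxorubicin, 86 and 42 for CVAD and cyclophosphamide between days, and 5 for saline. Of the 98, 40 were among the 76 of dexamethasone day 2 without replicate 3. Coding genes alone gave 7 for CVAD day 8 and 0 for the 3 drugs of day 2, cyclophosphamide day 8, CVAD against cyclophosphamide on day 2 and saline. Covariates gave 4 for CVAD day 2 and 0 for cyclophosphamide and dexamethasone day 2, CVAD against cyclophosphamide on day 2 and saline. The batch term gave 2 for CVAD day 2, 10 for CVAD day 8, 1 for CVAD against dexamethasone on day 8, 3 for dexamethasone day 2, 0 for CVAD against cyclophosphamide on day 2, 1 for CVAD and 1 for dexamethasone between days, and 3 for saline.

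With 1 library left out, counts ran from 0 to 4 (CVAD day 2), 0 to 3 (CVAD day 8), 0 to 2 (cyclophosphamide day 2), 0 to 4 (cyclophosphamide day 8), 0 to 76 (dexamethasone day 2), 0 to 3 (dexamethasone day 8), 0 to 7 (vincristine), 0 to 4 (doxorubicin), 0 to 2 (CVAD against cyclophosphamide and dexamethasone on day 2, and against vincristine, doxorubicin and dexamethasone on day 8), 0 to 3 (CVAD against cyclophosphamide on day 8), 0 to 24, 0 to 3 and 0 to 2 (CVAD, cyclophosphamide and dexamethasone between days) and 0 to 5 (saline).

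The correlation with CVAD at a pseudocount of 0.1 was 0.523 and 0.517 for cyclophosphamide and dexamethasone on day 2, and 0.547, 0.542 and 0.529 for cyclophosphamide, vincristine and doxorubicin on day 8. With an estimated correlation the calls ended, at the same means, for proliferation in CVAD day 8 (−0.614), neutrophil and proliferation in cyclophosphamide day 8 (−0.847 and −0.59), vincristine (−0.761 and −0.315) and doxorubicin (−0.593 and −0.209).

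Directions reversed with the batch term, in CVAD day 2, for Gm5539 (−0.006), Mmp9 (−0.037), Herpud1 (0.072), Cdc20 (−0.038), Aurkb (−0.039), Tsc22d3 (−0.076), Mki67 (−1.126), neutrophil (−0.425), interferon (−0.099), proliferation (−0.462), spinal cord (0.226) and endoplasmic reticulum (0.002). In cyclophosphamide day 2 they were Herpud1 (0.066), Aurkb (−0.092), Nr1d2 (0.107), Cdkn1a (0.036), Mki67 (−1.138), interferon (−0.107), proliferation (−0.5), Schwann cells (0.043), endoplasmic reticulum (0.025) and clock (0.026), and in dexamethasone day 2 H2-Ab1 (−0.082), Cdkn1a (0.049), Mki67 (−0.751) and MHC class II (−0.063). The neutrophil list between days in cyclophosphamide was 0.137. With quality weights cyclophosphamide day 2 had Fkbp5 at 0.033, Tsc22d3 at 0.041 and glucocorticoid at 0.018, cyclophosphamide day 8 Atf3 at −0.033, and vincristine, doxorubicin and dexamethasone day 8 Cdkn1a at −0.019, −0.107 and −0.032. Proliferation in CVAD against cyclophosphamide on day 8 was 0.031. Median-ratio scaling gave Fkbp5 −0.028 and Tsc22d3 −0.013 in CVAD day 2 and Cdkn1a 0.005 in cyclophosphamide day 8. Coding genes alone gave Fkbp5 0 in CVAD day 2. Covariates gave Cdkn1a 0.024, 0.07 and −0.084 in cyclophosphamide day 2, dexamethasone day 2 and doxorubicin, Mki67 −0.101 in dexamethasone day 8, glucocorticoid 0.011, Schwann cells 0.198 and clock 0.055 in cyclophosphamide day 2, Schwann cells −0.01 in cyclophosphamide day 8 and muscle 0 in vincristine, which the muscle covariate fixes at 0. Glucocorticoid in saline between days was 0.063 with quality weights and 0.057 with covariates.

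With 1 library left out these ranges crossed 0, or the list turned relative to the other genes, save proliferation in doxorubicin, whose call ended. Fkbp5 ran from −0.212 to 0.384 (CVAD day 2), −0.304 to 0.072 (cyclophosphamide day 8), −0.275 to 0.258 (cyclophosphamide day 2) and −0.453 to 0.08 (dexamethasone day 2). Tsc22d3 ran from −0.197 to 0.023 (cyclophosphamide day 8), −0.05 to 0.214 (CVAD day 2), −0.138 to 0.126 (cyclophosphamide day 2), −0.226 to 0.038 (dexamethasone day 2) and −0.009 to 0.105 (vincristine). Cdkn1a ran from −0.174 to 0.037 (dexamethasone day 2), −0.021 to 0.309 (CVAD day 8), −0.223 to 0.106 (cyclophosphamide day 8), −0.127 to 0.202 (dexamethasone day 8), −0.171 to 0.159 (doxorubicin) and −0.08 to 0.25 (vincristine). Atf3 ran from −0.411 to 0.154 (doxorubicin), −0.209 to 0.311 (cyclophosphamide day 8) and −0.505 to 0.015 (vincristine). In dexamethasone day 8 Mki67 ran from −0.372 to 0.324, Slc4a1 from −0.476 to 2.275 and Tnnt3 from −0.173 to 2.694. Among lists, red cell ran from −1.488 to 0.228 (CVAD day 2), −0.621 to 1.384 (cyclophosphamide day 8) and −0.367 to 1.638 (dexamethasone day 8). In CVAD day 8 mural ran from −0.207 to 0.051, respiratory chain −0.11 to 0.021, cholesterol −0.153 to 0.022, macrophage −0.262 to 0.029 and interferon −0.197 to 0.006. Proliferation ran from −0.128 to 0.163 in CVAD against cyclophosphamide on day 8 and −0.433 to −0.025 in doxorubicin. In cyclophosphamide day 8 Schwann cells ran from −0.062 to 0.278 and clock −0.024 to 0.312. Muscle in dexamethasone day 8 ran from −0.069 to 2.245, glucocorticoid −0.265 to 0.213 (cyclophosphamide day 2), −0.318 to 0.16 (dexamethasone day 2), −0.263 to 0.215 (saline between days), −0.055 to 0.454 (CVAD between days), and 0.002 to 0.371 and 0.055 to 0.424 (CVAD against cyclophosphamide and dexamethasone on day 2), p53 −0.272 to −0.012 (dexamethasone day 8 and doxorubicin) and −0.21 to 0.05 (vincristine), and tubulin −0.13 to 0.001 (vincristine).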

Other observations

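Tests in this part were chosen after the values were seen. Of eosinophil genes, Epx (eosinophil peroxidase) on day 8 was at 0 in each CVAD library and at 6.75, 5.79 and 3.46 TPM in saline. A set of such genes was at −1.99 ± 0.49 in CVAD and −1.71, −0.40, −0.48 and −0.23 in cyclophosphamide, vincristine, doxorubicin and dexamethasone. In saline that set rose by 1.48 ± 0.49 from day 2 to day 8.

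Within groups, over the 30 libraries, genes of granulocyte precursors followed those of mature neutrophils at r = 0.90, those of megakaryocytes at 0.69 and the proliferation list at 0.55. Permutation of libraries within groups gave adjusted p-values of 7e-05, 0.00327 and 0.0385. By rank the proliferation list had rho = 0.46, which did not pass (permutation test, adjusted p = 0.0805). With erythroid precursors r was 0.26 (permutation test, adjusted p = 0.406), or 0.46 without the 2 farthest libraries, and rho was 0.39 (permutation test, adjusted p = 0.126). With bone and cartilage r was 0.17 (permutation test, adjusted p = 0.42) and with red blood cells 0.15 (permutation test, adjusted p = 0.53).

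Saline replicate 3 of day 2 had the highest Fkbp5 and Atf3 of its group, at 96.5 and 27.1 TPM.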
